A study of Mus musculus with 2 samples.

How the data were processed

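Embryonic facial prominence, the tissue that forms the face, was taken from C57BL/6NCrl mouse embryos of both sexes at embryonic day 15.5. Chromatin was immunoprecipitated with an antibody against histone H3 trimethylated at lysine 9 (H3K9me3) and the DNA was sequenced (ChIP-seq). Per the labels, biological replicate 1 pooled tissue of 78 embryos and biological replicate 2 pooled tissue of 62 embryos, and each was made of 2 technical replicates. The labels give 1 group and no other condition, so no difference between conditions was tested. The question addressed was where in the genome the mark lay.

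The authors deposited 4 peak lists on the mouse assembly mm10. These are 1 list per biological replicate, 1 list of peaks called on both replicates pooled, and 1 list of replicated peaks which, per the labels and the text deposited beside the lists, was derived from the pooled list and the lists of both replicates. The signal value of each peak, deposited by the authors in the narrowPeak column order, was read as a fold enrichment, that is a linear ratio. The sources used here do not name its scale, and printed fold values rest on this reading. The significance of each peak was deposited by the authors as the −log10 of its p-value and, separately, of its q-value. The aligner, the peak caller and their settings are not given in the sources used here. The lowest −log10 p in any list was 2.00. Read numbers are not given in the lists, so the depth of each library is unknown, and a longer list can come from a deeper library. No control list was used here, though the labels name a possible control experiment. This does not mean that the authors called their peaks without a control. Fold enrichment and p of a replicated peak are those of the pooled libraries, carry no replicate error, and were used only to describe, rank, filter or compare peaks within a list.

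Positions were compared with the GRCm38 reference sequence, the same assembly as mm10, and with the gene models of GENCODE mouse release M21. Comparisons used chromosomes 1 to 19, X and Y. Peaks on unplaced or unlocalised scaffolds were left out of them. The replicated list was the main list. Positions are given counted from 1.

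The share of each replicate's peaks that overlapped a peak of the other by at least 1 bp, and the Jaccard index of the covered bases, were compared with 1000 circular shifts of 1 list along each chromosome (one-sided permutation test). A circular shift keeps the number, widths and clustering of the peaks. The shares of peak bases within 1 kb of a transcription start site (TSS), in exons, in introns and between genes, the share of soft-masked bases and the share of G and C were compared with 1000 shifts (two-sided permutation tests). The smallest p that these shifts can give is 0.001 one-sided and 0.002 two-sided. Exact matches to 4 retroviral primer binding sites were found on both strands of the genome. The sequences were TGGTGCCGAAACCCGGGA for tRNA-Phe, TGGGGGCTCGTCCGGGAT for tRNA-Pro, TGGCGCCCAACGTGGGGC for tRNA-Lys1,2 and TGGCGCCCGAACAGGGAC for tRNA-Lys3. The number of sites within 1 kb of a peak was compared with 1000 shifts (one-sided permutation test).

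For 17 gene lists, the share of protein-coding genes with a peak in the gene body was compared with 10000 random lists matched in 20 bins of gene length. This was a two-sided permutation test whose smallest p is 0.0002. The lists were zinc finger genes (symbols beginning Zfp, Zscan, Zkscan, Zik or Zim), olfactory receptors, vomeronasal receptors, clustered protocadherins, Hox genes, imprinted genes, germline genes, craniofacial transcription factors, and genes of cartilage and bone, muscle, surface epithelium, neurons, blood and endothelium, liver, pluripotency, the two-cell stage and housekeeping. The zinc finger list was chosen by symbol, and the KRAB domain of its members was not checked. A symbol carried by more than 1 gene model counted once per model, and symbols without a protein-coding model on the chromosomes were left out. Among zinc finger genes with a peak, the shares with a peak at the last exon and within 1 kb of the TSS were compared with those of length-matched genes with a peak. P-values were adjusted by the Benjamini-Hochberg method within each family of tests, with a threshold of 0.05. Intervals of shares are 95% Wilson intervals and cover counting error only. Genes and peaks are not independent replicates, so each p describes these lists against random placement and not the spread between animals.

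Peaks no more than 10 kb apart were joined into domains. Named genes were chosen by a rule set before the data were examined, as were the tests, the lists and most alternatives. The rule took the 15 protein-coding genes with the highest fold enrichment of a replicated peak in the gene body, the 10 with the most bases under replicated peaks, and up to 4 members per list with the highest fold enrichment. For a list with no such member it took up to 3 members without a peak. It also took the 5 peaks of highest fold enrichment and the genes of the 10 domains with the most bases under peaks. Where another gene is named, the text says so.

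Alternatives were peaks in the upper part of fold enrichment (at or above the median of the list), each replicate's own list, the pooled list, an overlap of 50% of the shorter peak, an equal number of the strongest peaks, autosomes only and random placement. For genes they were 5 kb flanks, TSS windows only, at least 200 bp of peak, and circular shifts. For domains they were gaps of 2 and 50 kb. Peaks with the authors' q under 0.05, replicated peaks that overlap both replicates by 50%, 100 length bins and first exons only were added after seeing the data.

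The computations were tested on simulated data. With 25% of peaks planted as shared, 25.5% were found shared, and 2 of 20 pairs of unrelated lists were called overlapping. Of 204 tests of the fixed gene lists without a planted change 5 were called, and all 100 lists with a planted rise of 25 percentage points were found. Simulated peaks fell on each gene independently in these tests. They therefore do not show how often lists of clustered or nested genes would be called without a change. Of 200 lists of 40 genes drawn in proportion to gene length 29 were called, so the 20 length bins leave part of the length effect in place for lists of long genes. Uniqueness of sequence was measured as the share of 50-mers, sampled every 25 bp, that occur once on both strands of the chromosomes. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and numba 0.67.0, and figures used matplotlib 3.10.9.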

Results

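H3K9me3, a histone mark of heterochromatin and of silenced genes and retroviruses, was measured by ChIP-seq in the facial prominence of mouse embryos at embryonic day 15.5. The data were 2 biological replicates of 1 group, with 18476 peaks in replicate 1 and 29091 peaks in replicate 2. The list called on both replicates pooled held 39188 peaks, and the list of replicated peaks held 8670. Replicated peaks had a median width of 416 bp and covered 4.61 Mb. Depth per library is unknown. The authors' signal value of the replicated peaks, read here as a linear fold enrichment, had a median of 3.10 and ranged from 1.51 to 8.34.

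The gamma protocadherins, cell adhesion proteins of neurons chosen from alternative first exons, lay in the domain with the most bases under replicated peaks. It spanned 120.4 kb of chromosome 18 (37657382 to 37777740) from Pcdhga1 to Pcdhga12 and held 67 peaks that covered 66.4% of it. The Ugt1a cluster on chromosome 1 (88211475 to 88257785), which encodes UDP-glucuronosyltransferases from Ugt1a10 to Ugt1a1, was next, with 20 peaks over 82.1% of 46.3 kb, and this domain also overlapped Mroh2a. A domain over Gm10775 and Zfp369 on chromosome 13 (65237222 to 65312294) held 41 peaks. The beta protocadherins Pcdhb15 to Pcdhb22 formed a further domain of 64.2 kb with 32 peaks (chromosome 18, 37473686 to 37537833).

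The other domains among the 10 with the most bases under peaks lay on chromosomes 3, 4, 7 and 10. Zfp329 and Zfp110 shared 1 on chromosome 7 (12808318 to 12854016), Vmn1r76 lay in another on chromosome 7 (11904368 to 12018045), and AU041133 lay in 1 on chromosome 10 (82117073 to 82165639). No protein-coding gene overlapped the domains on chromosome 3 (3000680 to 3038487, nearest gene Hnf4g) or on chromosome 4 (3049983 to 3091158, nearest gene Vmn1r2, and 121998309 to 122059505, nearest gene Gm12887). The domain on chromosome 3 and the first of those on chromosome 4 lay at the start of known sequence, which begins at 3000001 and 3050001. Without a control list, reads piled up on repeated sequence there are not separated from the mark. In all, 5432 domains were formed, of which 1086 held more than 1 peak, and these held 48.5% of the replicated peaks on chromosomes. The number with more than 1 peak was 2336 in replicate 1 and 4055 in replicate 2. With gaps of 2 kb the longest domain spanned 85.0 kb with 34.7% of peaks in domains of more than 1, and with gaps of 50 kb it spanned 808.6 kb with 65.3%.

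Klf14, a Krüppel-like transcription factor gene, carried the replicated peak with the highest fold enrichment, 8.34, on chromosome 6 (30957010 to 30958893). The peak lay inside the gene body (30956023 to 30959078), came within 1 kb of the TSS and did not reach it. Zfp865 carried a peak of 6.93 that reached an exon of the gene (chromosome 7, 5029295 to 5032557), in a stretch where the models of Ccdc106 and Gm44973 overlap Zfp865. Plec, the gene of the cytoskeletal linker plectin, had a peak of 6.79 that overlapped exons (chromosome 15, 76172427 to 76181291) that was also the widest of the replicated list at 8865 bp. An intron of 2610008E11Rik held a peak of 6.64 (chromosome 10, 79069614 to 79071842), 1 of 11 replicated peaks in that gene. The 5 peaks of highest fold enrichment included 3 between genes, at 3112846 to 3115892 (7.54) and 3117826 to 3119538 (6.85) on chromosome 18, nearest to Vmn1r238, and at 17903647 to 17904154 (6.79) on chromosome 12, nearest to Hpcal1. Each of these peaks overlapped a peak of both replicates by 50% of the shorter. Those on chromosome 18 lay near the start of its known sequence at 3000001, and no control list was used here.

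Clustered protocadherins were the list with the highest share of genes with a replicated peak, 50 of 57 (87.7%, interval 76.8 to 93.9), against 15.8% ± 4.54 (SD) in length-matched random lists. Zinc finger genes, many of which encode repressors of retroviruses, had a peak in 151 of 423 (35.7%, interval 31.3 to 40.4) against 6.59% ± 1.16. Imprinted genes, expressed from 1 parental allele, had a peak in 23 of 35 (65.7%, interval 49.2 to 79.2) against 10.4% ± 4.86. Vomeronasal receptors, which detect pheromones, had a peak in 50 of 327 (15.3%, interval 11.8 to 19.6) against 4.17% ± 1.08. For each of these 4 lists p was 0.0002, the smallest the two-sided permutation test can give, and the adjusted p was 0.00085. Against circular shifts of the peaks, which keep neighbouring genes together, the spread was wider, at 14.1% ± 16.8 for protocadherins, 7.33% ± 1.89 for zinc finger genes, 11.5% ± 5.30 for imprinted genes and 5.70% ± 2.36 for vomeronasal receptors. The adjusted p was then 0.0113 for the first 3 and 0.017 for vomeronasal receptors (two-sided permutation test). The share of all 21938 protein-coding genes with a peak was 8.14%.

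**Figure D1:**
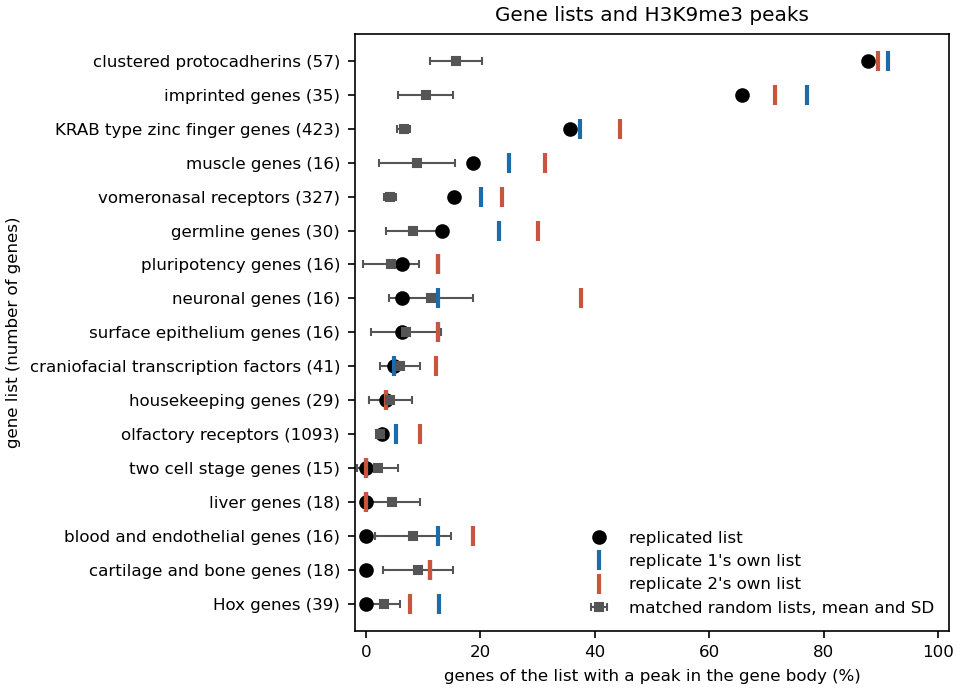
Percent of the genes of each list (number of genes in brackets) with a peak in the gene body. Black points are the replicated list, blue and red bars the lists of replicates 1 and 2, and grey squares with bars the mean and SD of 10000 length-matched random lists for the replicated list. Clustered protocadherins (87.7%), imprinted genes (65.7%), zinc finger genes (35.7%) and vomeronasal receptors (15.3%) lie apart from their matched lists.

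The same 4 lists lay above matched genes in each replicate's own list. These longer lists also reached more of the matched genes, so the ratios to matched genes were lower than in the replicated list. Protocadherins with a peak were 91.2% against 27.6% of matched genes in replicate 1 and 89.5% against 37.2% in replicate 2. Imprinted genes with a peak were 77.1% against 19.4% and 71.4% against 26.3%. Zinc finger genes with a peak were 37.4% against 11.9% and 44.4% against 16.2%, a ratio of 3.14 and 2.75 where the replicated list gave 5.41. Vomeronasal receptors with a peak were 20.2% against 7.63% and 23.9% against 10.5%. The adjusted p was at or below 0.00085 for each (two-sided permutation test). The bodies of the alpha and of the gamma protocadherin genes are nested, so that a single peak can count for many of them. Pcdhga1, Pcdhga2, Pcdhga3, Pcdhga4, Pcdhga5 and Pcdhga6 thus shared a peak of 6.34 (chromosome 18, 37720833 to 37722295), which was intronic in each. Pcdhga7, Pcdhgb1, Pcdhgb2 and the long models Gm42416, Gm37013 and Gm37388 also spanned this peak. It lay inside the first exon of Pcdhgb4 (37720369 to 37722917). Replicated peaks covered 78888 bp in Pcdhga1 and 51197 bp in Pcdhga6.

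Counted by the first exon of each gene, 48 of 57 protocadherins had a replicated peak (84.2%, interval 72.6 to 91.5) against 1.12% ± 1.40 in matched genes (adjusted p = 0.0017, two-sided permutation test). This count was chosen after seeing the data, and a few peaks still count for neighbours, such as that at 37518204 to 37518690, where the first exons of Pcdhb21 and Pcdhb22 overlap, and that at 37489414 to 37490344, which reaches Pcdhb17 and Pcdhb18. Genes were matched by gene length and not by exon length. Protocadherin first exons are long, as that of Pcdhga1 at 37661793 to 37665039, and a long exon is more readily overlapped by a peak. The alpha cluster had a peak at 10 of 14 first exons, the beta cluster at 20 of 22 and the gamma cluster at 18 of 21. Beta genes, which are not nested, also had a peak in 20 of 22 gene bodies, so counting by first exons left their number unchanged. Replicate 1 had a peak at 11, 22 and 18 of these first exons and replicate 2 at 10, 20 and 18.

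**Figure D2:**
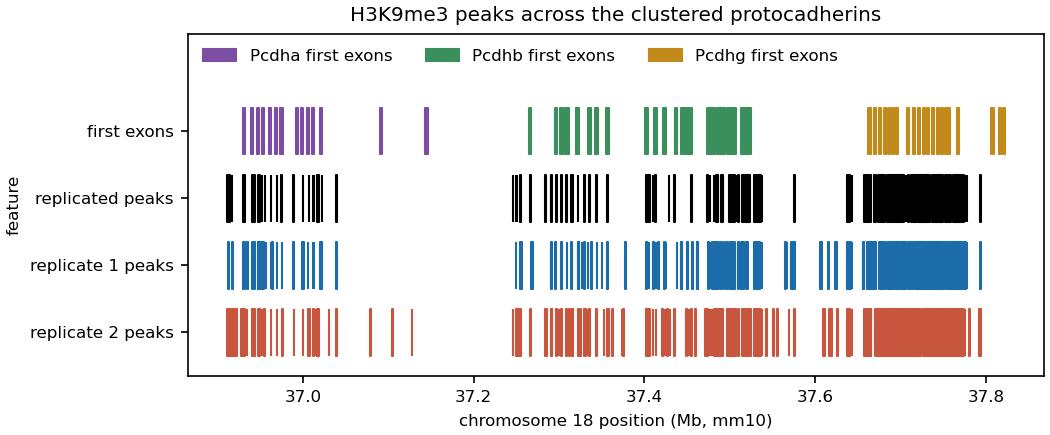
Map of the clustered protocadherins on chromosome 18 of mm10, with position in Mb on the horizontal axis. Bars mark the first exons of the alpha, beta and gamma genes and the peaks of the replicated list and of replicates 1 and 2, and features narrower than 0.8 kb are drawn at that width. Peaks are dense over the gamma first exons, where 18 of 21 carry a replicated peak.

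Among zinc finger genes, Zfp865 had the highest peak (6.93), followed by Zfp27 (6.34; chromosome 7, 29893214 to 29896076), Zfp810 (6.34; chromosome 9, 22276742 to 22277920) and Zfp329 (6.20; chromosome 7, 12809269 to 12812184), each over an exon. Zfp810 held 8 replicated peaks and Zfp329 held 6. Among vomeronasal receptors Vmn2r10 reached 4.43 and Vmn1r73, with 5 peaks, 3.91, while Vmn1r65 and Vmn1r82 both reached 3.69. With peaks overlapping both replicates, vomeronasal receptors with a peak fell to 23 of 327 (7.03%) against 2.48% ± 0.849, a ratio of 2.84 in place of 3.66, and still passed the test (adjusted p = 0.00085, two-sided permutation test). With peaks counted within 1 kb of the TSS only, vomeronasal receptors stood at 2.14% against 0.724% ± 0.463 in matched lists, a ratio of 2.96. This no longer passed the test (adjusted p = 0.0673, two-sided permutation test). At first exons vomeronasal receptors did not pass either (2 of 327, 0.612% against 0.445%, adjusted p = 1, two-sided permutation test).

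Imprinted genes held their peaks partly at promoters, with a peak within 1 kb of the TSS in 11 of 35 (31.4%) against 0.971% ± 1.64 in matched lists (adjusted p = 0.00113, two-sided permutation test). The 11 were Nnat, Gnas, Sgce, Peg10, Nap1l5, Peg3, Usp29, Magel2, Cdkn1c, Zrsr1 and Slc38a4, of which all but Gnas, Peg3 and Usp29 fall outside the rule for named genes and were named after their values were seen. Peg3, a zinc finger gene expressed from the paternal allele, and its neighbour Usp29 shared a peak of 4.72 at their adjoining starts (chromosome 7, 6728262 to 6730653). Grb10, a growth factor receptor adaptor, had 6 peaks up to 4.76 (chromosome 11, 12025327 to 12026338, exonic), and Gnas, the gene of a stimulatory G protein subunit, had 8 peaks up to 4.72 (chromosome 2, 174298187 to 174299097, exonic). Of the non-coding members, Nespas reached 4.28 and Meg3 3.10 at their starts, and Airn and Kcnq1ot1 both reached 3.69.

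Germline genes had a replicated peak in 4 of 30 gene bodies (13.3%, interval 5.31 to 29.7) against 8.23% ± 4.84 in matched lists, which did not pass the test (adjusted p = 0.911, two-sided permutation test). All 4 peaks lay within 1 kb of the TSS, where matched lists had 0.799% ± 1.63 (adjusted p = 0.00113, two-sided permutation test). Counted by first exons only, 2 of 30 had a peak (6.67%) against 0.473% ± 1.25, which did not pass the test (adjusted p = 0.0782, two-sided permutation test). The 4 genes were Dazl, an RNA-binding protein of germ cells (3.22; chromosome 17, 50293153 to 50293887), Taf7l (2.95; chromosome X, 134475062 to 134475699), Tuba3a (2.95; chromosome 6, 125284684 to 125285300) and Ddx4, the Vasa helicase (2.53; chromosome 13, 112652034 to 112652409). Each of the 4 peaks overlapped a peak of both replicates by 50% of the shorter.

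Craniofacial transcription factors had a peak in 2 of 41 (4.88%, interval 1.35 to 16.1) against 5.93% ± 3.49, at introns of Runx2 (2.93) and Prrx1 (2.84). Cartilage and bone genes, such as Col2a1, Acan and Col9a1, had a peak in 0 of 18 (interval 0 to 17.6%) against 9.10% ± 6.19, and Hox genes, such as Hoxa1, Hoxb1 and Hoxc4, in 0 of 39 (interval 0 to 8.97%) against 3.13% ± 2.78. Muscle genes had a peak in 3 of 16 (18.8%) against 8.92% ± 6.65, namely Ttn (3.98, 9 peaks), Cacna1s (3.39) and Mybpc1 (3.39). None of these lists passed the test (adjusted p from 0.866 to 1, two-sided permutation test). For the Hox list and the cartilage and bone list 0 is the lowest possible count. The test in the replicated list thus could not have shown fewer peaks in them than in matched genes. The lists of replicates 1 and 2 had peaks in 5 and 3 Hox genes and in 2 cartilage and bone genes each. In the pooled list cartilage and bone genes with a peak were 0 of 18 against 24.8% ± 8.45, below matched genes (adjusted p = 0.00623, two-sided permutation test).

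Markers of other cell types and stages did not pass the test either. Where a list had a peak in 0 genes, the lowest possible count, the test could not have shown fewer peaks than in matched genes. Surface epithelium genes had a peak in 1 of 16 (Dsp, 4.17), neuronal genes in 1 of 16 (Rbfox3, 3.69), pluripotency genes in 1 of 16 (Esrrb, 3.00) and housekeeping genes in 1 of 29 (Tbp, 2.95). Blood and endothelial genes, such as Alas2, Gypa and Ptprc, had a peak in 0 of 16, liver genes, such as Alb, Afp and Apoa1, in 0 of 18, and genes of the two-cell stage, such as Zscan4c, Zscan4d and Zscan4f, in 0 of 15. Olfactory receptors had a peak in 31 of 1093 (2.84%) against 2.44% ± 0.433, led by Olfr138 (3.98), Olfr115 (3.84), Olfr77 (3.69) and Olfr943 (3.54). In the list of replicate 2 olfactory receptors with a peak were 9.42%, above matched lists (adjusted p = 0.00068, two-sided permutation test), and in that of replicate 1 they were 5.22% (adjusted p = 0.293). They also lay above matched lists in the pooled list (11.5% against 6.90%, adjusted p = 0.00068) and, in the replicated list, with 5 kb added on each side of the gene (6.95% against 4.83%, adjusted p = 0.00544, two-sided permutation test for both).

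Zinc finger genes carried their peaks at the 3′ end. Of the 151 with a replicated peak, 105 had a peak at the last exon (69.5%) against 38.9% ± 3.14 of length-matched genes with a peak, and 7 had a peak within 1 kb of the TSS (4.64%) against 8.36% ± 1.90. The last exon alone was marked in 100 of these genes and the TSS alone in 2. With a window at the TSS as long as the last exon of each gene, 19 of the 151 had a peak there (12.6%) against 14.4% ± 2.38 of matched genes (adjusted p = 0.535, two-sided permutation test), and the last exon alone was marked in 92 and the TSS window alone in 6. The share at the last exon passed the two-sided permutation test (adjusted p = 0.0004) and the share at the TSS did not (adjusted p = 0.0646). Matching was by gene length and not by the length of the last exon, and a long exon is more readily overlapped by a peak. The comparison with matched genes therefore does not separate exon length from placement at the 3′ end. The window as long as the last exon compares both ends within a gene only. The last exon was marked in 73.4% of zinc finger genes with a peak in replicate 1 and in 66.0% in replicate 2. Few of all 423 zinc finger genes had a peak within 1 kb of the TSS, 9 (2.13%), but these were above the 0.594% ± 0.375 of length-matched lists (adjusted p = 0.0119, two-sided permutation test). With peaks counted at first exons only, 0.946% had a peak against 0.363% ± 0.291, which did not pass the test (adjusted p = 0.458, two-sided permutation test).

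Murine leukaemia virus type elements, whose primer binding site matches tRNA-Pro, had a replicated peak within 1 kb at 35 of 174 sites (20.1%, interval 14.8 to 26.7) against a mean of 0.561% and a highest value of 3.45% in shifted lists. Sites for tRNA-Lys1,2 had a peak nearby at 9 of 67 (13.4%, interval 7.23 to 23.6) and sites for tRNA-Lys3, used by mouse mammary tumour virus, at 4 of 62 (6.45%, interval 2.54 to 15.5). Sites for tRNA-Phe, used by intracisternal A particles, had a peak nearby at 38 of 1090 (3.49%, interval 2.55 to 4.75) against 0.720% in shifted lists. Each adjusted p was 0.001, the smallest the one-sided permutation test can give. The tRNA-Pro share was 20.1% in replicate 1 and 25.3% in replicate 2, and the tRNA-Phe share 6.24% and 7.62%. In the pooled list the tRNA-Phe share was 13.6% against 2.84% in shifted lists. It was 1.74% against 0.392% with peaks overlapping both replicates, and 1.56% against 0.404% with peaks in the upper part of fold enrichment. The tRNA-Lys1,2 share was 11.9% in replicate 1 and 29.9% in replicate 2, and the tRNA-Lys3 share 12.9% and 9.68%.

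The peak lay over the tRNA-Pro site itself at 11 of 174 sites (6.32%) and over the tRNA-Phe site at 0 of 1090. Around tRNA-Phe sites the bases under peaks rose to 2.40% between 1000 and 500 bp upstream, against a highest value of 0.573% in shifted lists. In this stretch 80.3% of 50-mers occurred once in the genome, against 18.6% in the 500 bp downstream of the site. For tRNA-Lys3 the excess was no longer past the test with peaks that overlap both replicates (1.61%, adjusted p = 0.249, one-sided permutation test).

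**Figure D3:**
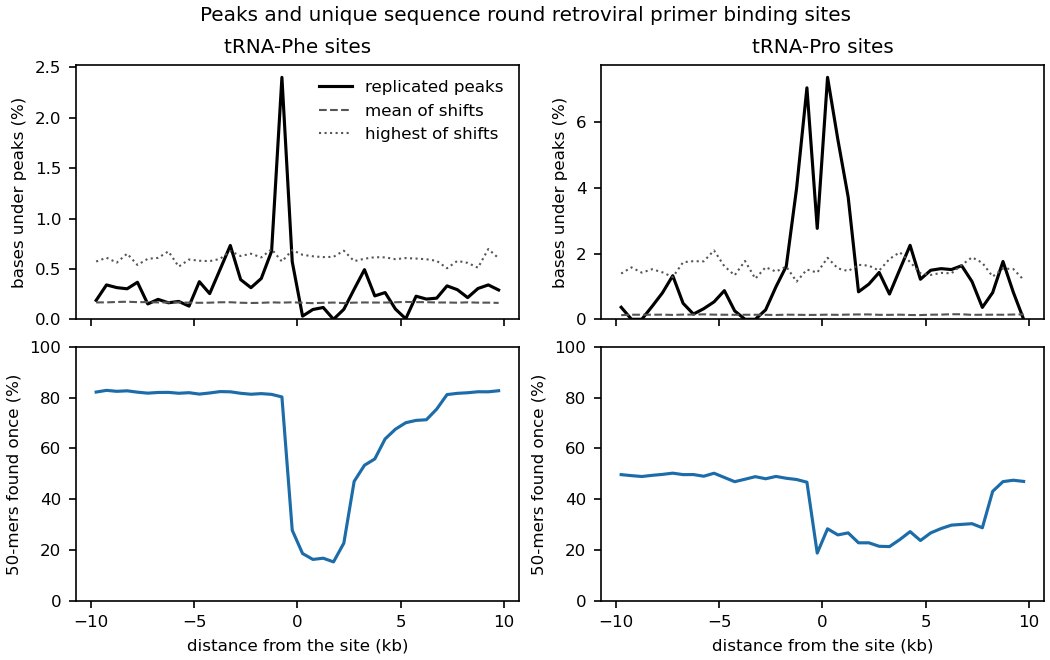
Percent of bases under replicated peaks (upper row) and percent of 50-mers that occur once in the genome (lower row) in bins of 500 bp by distance in kb from tRNA-Phe and tRNA-Pro primer binding sites, oriented along the element. Black lines are the replicated list, dashed and dotted grey lines the mean and the highest value of 1000 shifted lists. The highest bin is 2.40% upstream of tRNA-Phe sites and 7.38% downstream of tRNA-Pro sites.

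Exons held 11.8% of the bases under replicated peaks, against 4.23% ± 0.365 in shifted lists, and stretches within 1 kb of a TSS held 7.28% against 4.15% ± 0.350. Introns held 34.4% against 41.9% ± 1.93. Each of these passed the two-sided permutation test (adjusted p = 0.00266). Stretches between genes held 46.5% against 49.7% ± 2.05 and did not pass the permutation test (adjusted p = 0.120), and in the pooled list they held 52.6%, above the shifted lists (adjusted p = 0.028). Soft-masked repeats made up 30.2% of bases under peaks against 33.8% ± 0.819, and G and C 45.7% against 42.1% ± 0.300, with p = 0.002 for both, the smallest the two-sided permutation test can give. Of 50-mers under replicated peaks 97.6% occurred once in the genome, against 86.0% at random places. Shifted lists can land on sequence with several copies, so the lower repeat share does not show that the mark avoids repeats.

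Chromosome 7 held 4357 bp under replicated peaks per Mb of known sequence, 2.62 times the 1665 bp of all chromosomes. The ratio was 2.35 in replicate 1 and 2.03 in replicate 2. Chromosome 17 followed at 2.18 times, and chromosomes 18, 4 and 13 lay at 1.56, 1.55 and 1.5 times. Chromosome X lay at 0.195 times, with 0.220 in replicate 1 and 0.218 in replicate 2, and chromosome Y at 0.0391 times. Embryos of both sexes were pooled, so the sex chromosomes were on average present in fewer copies than autosomes. They also hold more repeats. Soft-masked bases were 84856465 of 88124698 known bases on chromosome Y and 76430888 of 163487995 on chromosome X, against 50229217 of 141855407 on chromosome 7. The values per chromosome were not tested, nor were copy number or repeats as the source of low values.

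**Figure D4:**
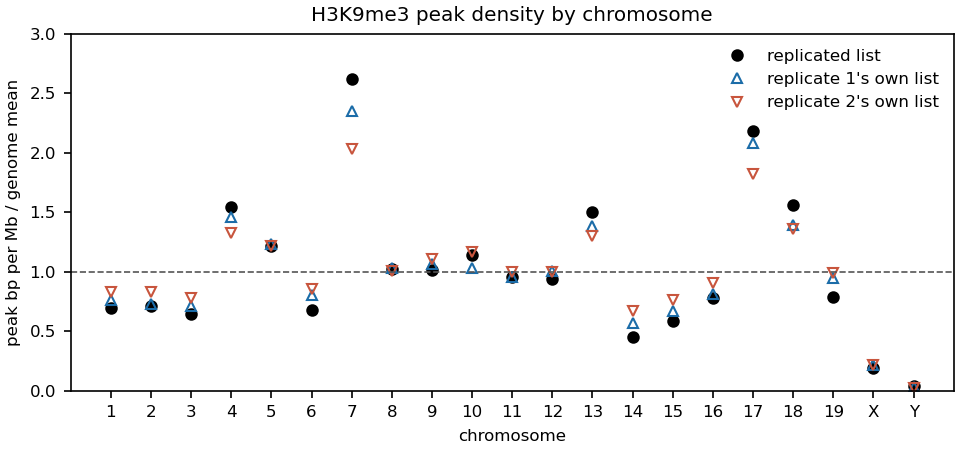
Bases under peaks per Mb of each chromosome divided by the value of all chromosomes, with the dashed line at 1. Black points are the replicated list and open triangles the lists of replicates 1 and 2. Chromosome 7 is highest at 2.62 and chromosomes X and Y are lowest at 0.195 and 0.0391.

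Peaks of the replicates overlapped far more often than shifted lists. Of the 18169 peaks of replicate 1 on chromosomes, 4628 (25.5%) overlapped a peak of replicate 2, against 0.683% ± 0.101 in shifted lists, and 16.4% of the peaks of replicate 2 overlapped a peak of replicate 1, against 0.433% ± 0.0641. The Jaccard index of covered bases was 0.103 against 0.00137. For each, p was 0.001, the smallest the one-sided permutation test can give. Of the strongest 10% of peaks by −log10 p, 63.4% (interval 61.1 to 65.6) were found again for replicate 1 and 44.8% (interval 43.0 to 46.6) for replicate 2, against 16.4% and 8.31% of the weakest 10%. Ranked by fold enrichment instead, the strongest 10% were found again in 53.7% for replicate 1 and 38.5% for replicate 2 and the weakest 10% in 27.2% and 15.2%, and in replicate 1 the weakest group lay above the next 7, which ranged from 12.8% to 26.7%. Both rankings hold ties, which were split by position.

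**Figure D5:**
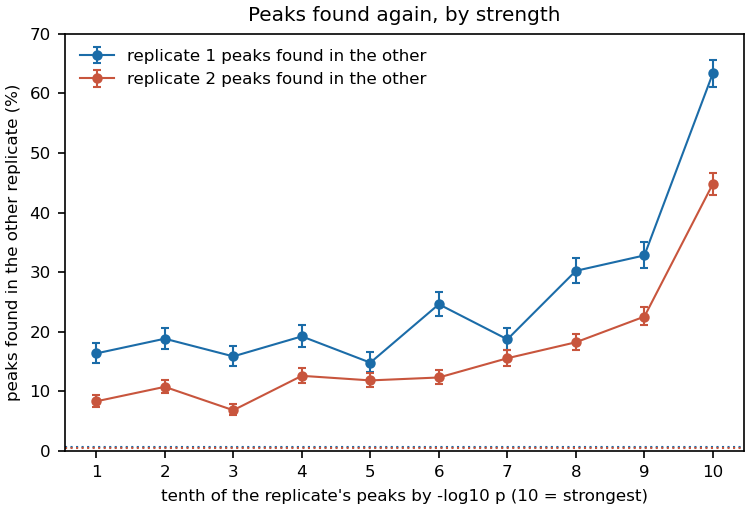
Percent of each replicate's peaks that overlap a peak of the other, in 10 equal groups by −log10 p from weakest (1) to strongest (10), with 95% Wilson intervals. Dotted lines near 0 are the means of shifted lists. The strongest group reaches 63.4% for replicate 1 and 44.8% for replicate 2.

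All 8670 replicated peaks were peaks of the pooled list, 22.1% of it (interval 21.7 to 22.5). Of these, 4512 (52.0%) overlapped a peak of both replicates by 50% of the shorter, 3712 a peak of 1 replicate only and 446 a peak of neither. No other pooled peak overlapped both replicates in this way. How the 4158 replicated peaks without such an overlap entered the list is not given in the sources used here. The peak of Runx2 and the strongest peaks of Mybpc1 and Meg3 were among those that did not overlap both replicates. Those of Klf14, Plec, Peg3 and Dazl did.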

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

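Unplaced and unlocalised scaffolds, which no comparison used, held 233 of the 8670 replicated peaks (2.69%), with 59 on a single scaffold that reached a −log10 p of 99.9. They are listed because they lie outside the main measurement. No control list was used here, so these values do not separate the mark from reads piled up on repeated sequence. The tests of explanations below were set before their results were seen, except the look at pooled peaks outside the replicated list, which was added after. With 1 group in the design, no biological explanation was tested.

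Zinc finger genes carried 170 replicated peaks at their last exons. The exons are alike between family members, so reads shared among copies were weighed as a source. Under these peaks 98.6% of 50-mers occurred once in the genome, as did 97.6% under all replicated peaks and 86.0% at random places. Exact copies of 50 bp were thus rare under these peaks, which argues against reads shared by exact copies as the source. The bound set beforehand lay below the share at random places, so passing it says little. The aligner is not given, and reads shared by near copies were not tested. Soft-masked bases made up 19.2% of bases under the last-exon peaks against 30.2% under all replicated peaks, between the bounds set beforehand. Repeats in or beside the exon thus stay open for a part of these peaks.

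Intracisternal A particle sites, marked by the tRNA-Phe primer binding site, had peaks upstream of the element and hardly any inside it. If reads with more than 1 place in the genome were left out, coverage would follow unique sequence, and Spearman's rho across the 40 bins of 500 bp was 0.358, between the bounds of 0.5 and 0 set beforehand. That explanation may hold for the element itself, but the bins far upstream are as unique as the marked bin, and the test cannot tell. Bases under peaks 8 to 10 kb from the site were 0.287% against a mean of 0.168% and a highest value of 0.408% in shifted lists (one-sided permutation p = 0.029), so a mark confined to the near flank was neither excluded nor shown.

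Of the replicated peaks on chromosomes, 4126 did not overlap a peak of both replicates by 50% of the shorter. Their median −log10 p was 5.52 against 7.28 in the other 4311, a difference of -1.76 that leaves open whether they lay near the threshold of each replicate. The split by calls in the replicates goes with pooled significance by itself: among pooled peaks outside the replicated list, the median was 3.95 without and 4.45 with a call in a replicate. As a set the 4126 were not placed at random, since 19 tRNA-Phe sites lay within 1 kb of them against a highest value of 11 in 1000 shifted lists. Without a control list this does not separate the mark from reads piled up near repeated sequence. How many single peaks among the 4126 are chance calls stays open.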

How the results depend on the processing

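Of 354 values under alternatives, 291 kept their direction and their side of the threshold or moved by less than the spread, 24 moved, 9 newly passed the threshold, 5 no longer passed it and 25 changed direction. Replicate overlap, exon, intron and TSS shares, repeat and GC content, the last-exon share of zinc finger genes, and the tRNA-Phe and tRNA-Pro excess kept their side under each alternative list of peaks that was run. Depth is unknown and limits what a missing peak shows. Except where an alternative by its construction uses fewer or more peaks, the cause was not tested. Peaks with the authors' q under 0.05, peaks overlapping both replicates, 100 length bins and first exons were chosen after seeing the data.

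With peaks in the upper part of fold enrichment, the lists held 11115 peaks in replicate 1, 15873 in replicate 2, 19938 in the pooled list and 4591 in the replicated list. The replicated share of pooled peaks rose to 37.5%, chromosome X fell to 0.149 times the genome, domains with more than 1 peak fell to 549, and the share between genes passed the test at 42.8% (adjusted p = 0.00799, two-sided permutation test). Germline (3.33%), surface epithelium (6.25%) and pluripotency (0%) lists changed direction without passing the test. With q under 0.05 the lists held 5553, 6841 and 22093 peaks in replicates 1 and 2 and the pooled list, chromosome X lay at 0.187, and zinc finger genes fell below matched genes at the TSS (4.00%, adjusted p = 0.0328, permutation test).

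With each replicate's own list, ranges were 2.03 to 2.35 for chromosome 7, 0.218 to 0.220 for chromosome X, 49.8% to 51.9% between genes, 2336 to 4055 domains, 7.69% to 12.8% of Hox genes, 12.5% to 12.5% of surface epithelium genes and 12.5% to 37.5% of neuronal genes. With the pooled list, chromosome X lay at 0.181, the share between genes turned upward to 52.6%, domains rose to 6013, olfactory receptors newly lay above matched genes (11.5%, adjusted p = 0.00068, permutation test), which made 5 such lists, 1 list (cartilage and bone) lay below, and Hox (15.4%), craniofacial (19.5%) and neuronal (37.5%) lists turned upward without passing the test.

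With peaks overlapping both replicates, chromosome X lay at 0.211, domains numbered 495, the share between genes was 41.3% (adjusted p = 0.00266, permutation test), zinc finger genes fell below matched genes at the TSS (3.42%, adjusted p = 0.0152), vomeronasal receptors fell to 7.03% and stayed above matched genes, and tRNA-Lys3 sites no longer passed (1.61%). With a TSS window as long as the last exon, zinc finger genes did not differ past the threshold (12.6%, adjusted p = 0.535, permutation test). Olfactory (1.37%), surface epithelium (6.25%) and housekeeping (3.45%) lists changed direction without passing. With the site inside the peak, tRNA-Lys1,2 no longer passed (1.49%), and tRNA-Lys3 and tRNA-Phe stood at 0%, below the mean of shifted lists (0.197% and 0.175%) by less than 2 SD.

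With 5 kb flanks olfactory receptors newly passed the test (6.95% against 4.83%, adjusted p = 0.00544, permutation test), and the pluripotency list changed direction at 6.25%, as did surface epithelium (6.25%) against circular shifts. With the TSS alone, zinc finger genes stayed above matched genes (2.13%, adjusted p = 0.0119, permutation test), and olfactory (0.915%), muscle (0%) and pluripotency (0%) lists changed direction. With first exons only, 2 lists lay above and 1 below matched genes, zinc finger genes (0.946%) and vomeronasal receptors (0.612%) no longer passed, germline genes did not pass (6.67%, adjusted p = 0.0782, permutation test), olfactory receptors fell below matched genes (0.0915%, adjusted p = 0.0215, permutation test), and muscle (0%) and pluripotency (0%) lists changed direction.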

Other observations

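Other gene families in clusters also held peaks. Among 270 families defined by a shared symbol stem and at least 10 genes, a grouping chosen after the data were seen, Skint genes, which encode immunoglobulin-like proteins of skin and thymus epithelium, had a replicated peak in 8 of 11 (72.7%) against 16.6% ± 10.6 in length-matched lists (adjusted p = 0.00771, two-sided permutation test). Ceacam cell adhesion genes had a peak in 6 of 15 (40%) against 4.36% ± 5.21, with the same adjusted p. Nlrp genes, sensors of the innate immune system and of the oocyte, had a peak in 7 of 17 (41.2%, adjusted p = 0.024), Ugt genes in 9 of 22 (40.9%, adjusted p = 0.024) and Sult sulfotransferase genes in 7 of 21 (33.3%, adjusted p = 0.0324, two-sided permutation test for each). Neighbouring genes of a family share domains and, in the Ugt1a cluster, exons, so the genes of a family are not independent of each other. Ugt1a10, Ugt1a9, Ugt1a8, Ugt1a7c, Ugt1a6b, Ugt1a6a, Ugt1a5, Ugt1a2 and Ugt1a1 all overlapped the single domain on chromosome 1. The Ugt count can therefore rest on that locus alone, and its p, from genes drawn independently, does not account for this.

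Zinc finger genes with a replicated peak differed in share between chromosomes, a count that was not tested. On chromosome 9 they were 13 of 20, on chromosome 4 they were 18 of 32, on chromosome 13 they were 20 of 41, on chromosome 17 they were 18 of 47 and on chromosome 7 they were 34 of 104. On chromosome 6 they were 2 of 17, and on chromosomes 1 and 14 they were 0 of 4 and 0 of 5.

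The 10 replicated peaks of lowest p ranged in fold enrichment from 2.34 to 5.82, so that the order by p was not the order by fold enrichment. On chromosome 11 the peak at 3190998 to 3195396 had a −log10 p of 106.2 and a fold enrichment of 2.88. The peaks at 3195459 to 3197214 and 3197435 to 3200117 of the same stretch were also among the 10. So were peaks at 62182 to 68602 and 31183 to 31972 of the unplaced scaffold JH584304. On chromosome 7 the peak at 12010301 to 12010980 had 90.2 and 4.57, on chromosome 13 that at 119597597 to 119598247 had 89.9 and 3.97, and on chromosome X that at 170008966 to 170010037 had 85.8 and 5.82. On chromosome 2 the peak at 98666133 to 98667406 had 84.9 and 2.88, and on chromosome 17 that at 39842984 to 39846769 had 81.5 and 2.34. The Klf14 peak, by comparison, had a −log10 p of 39.2 and a fold enrichment of 8.34. Without a control list, a very low p does not separate the mark from reads piled up on repeated sequence.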
